A study of Homo sapiens with 12 samples.

How the data were processed

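Gene expression was measured by RNA sequencing in 12 libraries of the human renal carcinoma line Caki-1. Per the labels' protocols, total RNA was extracted with an RNeasy kit, libraries were made with oligo-dT and reads were paired-end. Per the submitters' processing notes, cutadapt 1.13, STAR, HTSeq 0.6.1p1 and DESeq2 were used and the genome builds hg19 and mm10 are named, without saying what each was used for. The versions of STAR and DESeq2 and the strand setting are not given in the sources used here, so overlapping and antisense genes, paralogs and pseudogenes may share reads. The deposited values are whole-number counts per Ensembl gene ID, 1 table per library with 35700 human gene IDs, not normalized and without summary lines.

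Libraries were grouped by their labels, 4 labelled WT, 4 labelled KO1 and 4 labelled KO2. The labels give no replicate numbers, so libraries were numbered within a label in the order of deposit, a number that only names a library and pairs none. GENCODE 29, whose build differs from those named by the submitters, was used for gene symbols, gene types, the chromosome and order of genes and the GC content of transcripts. Of the 35700 IDs, 24635 were found there, and no coordinates are given because the builds differ.

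Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0 and sva 3.50.0, and plots were drawn in Python 3.11.15 with numpy 2.4.6 and matplotlib 3.10.9. Genes with low counts were removed with edgeR's filterByExpr by label, which left 14302 genes holding 99.95% of the counts. Library sizes were scaled by TMM. KO1 against WT, KO2 against WT and KO1 against KO2 were tested in 1 fit of all 12 libraries with edgeR's quasi-likelihood test (robust), two-sided, and a gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 with SE, and intervals are 95%. Library depth was 21015037 to 28247668 counts, and the median SE of a log2 fold change was 0.124 in KO1 against WT, 0.123 in KO2 against WT and 0.124 in KO1 against KO2. Simulated counts for KO1 against WT over 14302 genes were drawn independently for each library. Of the genes with a log2 mean CPM of at least 1, 200 were changed. The test recovered 0% of changes of 1.25-fold, 47% of 1.5-fold, 84.5% of 2-fold and 98% of 4-fold, and called 0, 2, 8 and 10 unchanged genes.

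The test designs, the first alternatives listed below, the rule for named genes and 36 gene lists were fixed before the data were examined. The lists cover lipid and phosphoinositide metabolism, signalling, cell cycle, stress, immune, matrix and nephron genes, markers of other cell types and the neighbours of MBOAT7. The 32 lists with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided and adjusted over lists within a comparison. The fibroblast, endothelial and leukocyte lists had 3 tested members each and the mitochondrially encoded list had 0, so these were not tested as lists. The rule for named genes took MBOAT7 and otherwise only genes called by edgeR. Since no gene was called, every other gene named was chosen after its values were seen, as 1 of the 10 genes of smallest p per comparison, 1 of the 40 genes of largest standard deviation over libraries among those with a mean log2 CPM of at least 3, or an example from a list. Among these, 2 genes are not reported here.

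Principal components were taken from log2 CPM of the tested genes. For each chromosome, and for windows of 40 genes along it, the median over genes of log2 CPM relative to each gene's median over libraries was taken. Those of chromosomes 7 and 13 were set beside 10000 random gene lists of the same size matched on expression. The share of variance by label was compared with all partitions of the libraries into 3 groups of 4.

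Alternatives fixed at the outset were other scaling factors (RLE, upper quartile, library totals), no filter or a CPM of at least 1 in 4 libraries, DESeq2's Wald test, limma voom, a test against a fold change of 1.5, a minimum absolute log2 fold change of 1, a fit of only the groups compared, leaving out each library in turn, and for lists an estimated correlation and limma's fry. Chosen after seeing the data were the first 2 principal components as covariates, 2 surrogate variables from svaseq as covariates, removal of each library's trend on transcript GC (lowess span 0.3), components with the GC trend removed, and leaving out the 4 libraries that stand apart on the first component. No file was left out, and reads were not analysed here.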

Results

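Transcript levels were measured by RNA sequencing in Caki-1, an established human clear cell renal carcinoma line grown in McCoy's medium with fetal bovine serum. The series concerns loss of function of MBOAT7, the lysophosphatidylinositol acyltransferase that places arachidonate on phosphatidylinositol. Its design text describes knockout clones made with CRISPR/Cas9, checked by Sanger sequencing and western blotting, and sequenced beside a wild-type counterpart. The 12 libraries carry 3 labels, with 4 libraries labelled WT, 4 labelled KO1 and 4 labelled KO2. Total counts were 25583559, 24997021, 27858832 and 24218776 in the libraries labelled WT 1 to WT 4, 23569382, 23912373, 23525118 and 22962459 in KO1 1 to KO1 4, and 26553133, 28247668, 23969671 and 21015037 in KO2 1 to KO2 4. The labels do not say whether the libraries of 1 label came from separate cultures. The p-values below therefore measure only the spread between these samples, which may be technical. In the main test, which has no covariates, that spread includes the large differences between libraries of 1 label described below. A gene that was not called is therefore not shown to be unchanged.

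MBOAT7 (ENSG00000125505, chromosome 19) was transcribed at a similar level under all 3 labels. Its level was 103, 143, 106 and 102 CPM (counts scaled to library size) in the libraries labelled WT 1 to WT 4, 124, 111, 137 and 95.2 CPM in KO1 1 to KO1 4, and 156, 126, 112 and 123 CPM in KO2 1 to KO2 4. Within the labels it was 124 to 156 CPM in WT 2, KO1 1, KO1 3 and KO2 1. It was 95.2 to 112 CPM in WT 1, WT 3, KO1 4 and KO2 3, and 102 to 126 CPM in WT 4, KO1 2, KO2 2 and KO2 4. The means were 113.5 ± 19.7 CPM (SD, n = 4) for WT, 117 ± 17.9 CPM (SD, n = 4) for KO1 and 129 ± 18.7 CPM (SD, n = 4) for KO2, resting on 2177 to 4163 counts per library. The log2 fold change was 0.04 in KO1 against WT (SE 0.14, 95% interval −0.27 to 0.35, edgeR adjusted p = 0.987) and 0.19 in KO2 against WT (SE 0.14, 95% interval −0.13 to 0.50, edgeR adjusted p = 1). With the first 2 principal components as covariates, a setting chosen after seeing the data, the KO1 value was −0.08 and the KO2 value was 0.17 (edgeR adjusted p = 0.0389). With each library's GC trend removed as well, the values were 0.00 and 0.08, and KO2 was no longer called (edgeR adjusted p = 0.353). A frameshift edit need not lower the amount of its transcript, so this level does not check the labels, and reads over the edited site were not analysed here. Groups are therefore named below as the libraries labelled WT, KO1 or KO2.

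**Figure D1:**
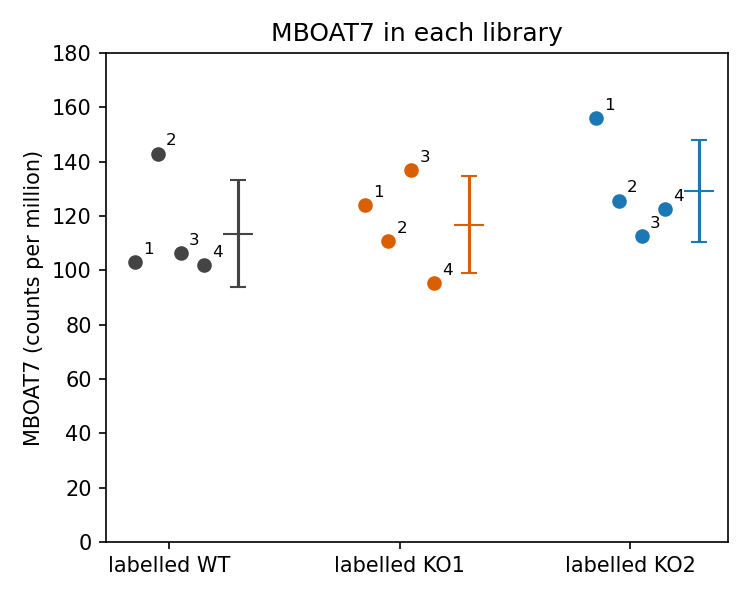
MBOAT7 level in CPM in each of the 12 libraries, grouped by label and numbered by replicate, with the mean and SD of each label beside the points. Values run from 95.2 to 156 CPM and the 3 labels overlap.

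The largest expression differences among the 12 libraries crossed the labels. The first principal component of log2 CPM held 57.8% of the variance and was 43.9 in WT 2, 45.2 in KO1 1, 44.5 in KO1 3 and 43.8 in KO2 1, against −24.8 to −19.9 in the other 8 libraries. The second component, with 16.9%, was 21.9 in WT 4, 22.4 in KO1 2, 17.1 in KO2 2 and 18.4 in KO2 4, and −21.2 in WT 1, −22.1 in WT 3, −19.3 in KO1 4 and −22.5 in KO2 3. Of the 12 libraries, 6 correlated best with a library of their own label. The label accounted for 12.3% of the variance between libraries. Of the 5775 ways to divide the libraries into 3 groups of 4, 3397 gave at least as much (exact p = 0.588), with a median of 15.3% and a maximum of 74.6%. The closest pair, WT 4 and KO1 2, had a chi-square of 1.79 per degree of freedom over genes, against 2.77 for WT 1 and WT 3 and 50.7 for WT 1 and WT 2. No library was therefore treated as another one sequenced again. This value cannot tell whether 2 libraries were prepared from the same RNA or culture.

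**Figure D2:**
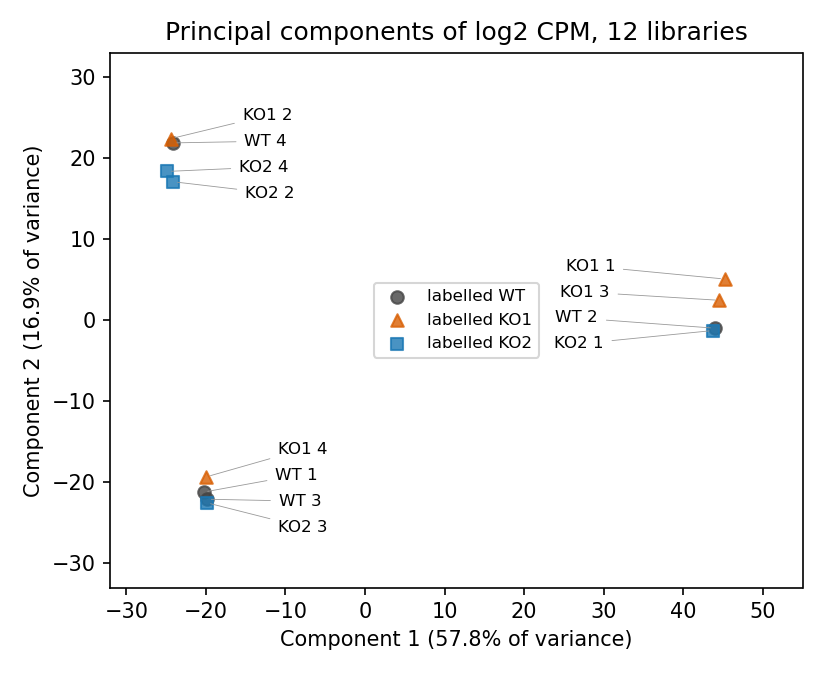
First and second principal components of log2 CPM over 14302 genes for the 12 libraries, with the share of variance on each axis and the label given by colour and shape. Libraries of each label appear in 3 separate places, and the first component is 43.8 to 45.2 in WT 2, KO1 1, KO1 3 and KO2 1.

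The genes with the largest spread, chosen after their values were seen by their standard deviation over the 12 libraries, followed the same 3 sets. FBN1, which encodes the microfibril protein fibrillin-1, had a log2 CPM of 5.96 in WT 2, 6.12 in KO1 1, 5.74 in KO1 3 and 5.94 in KO2 1, and of 10.15 to 10.50 in the other 8 libraries. CDH6, a cadherin of the kidney proximal tubule, had 5.86, 5.91, 6.01 and 5.96 in the same 4 libraries and 9.66 to 9.80 elsewhere. FN1, which encodes the matrix protein fibronectin, had 9.43, 9.52, 9.19 and 9.23 in those 4 libraries, 4.77 in WT 4, 4.78 in KO1 2, 4.70 in KO2 2 and 4.74 in KO2 4, and 8.01 to 8.24 in WT 1, WT 3, KO1 4 and KO2 3. The neutrophil chemokine CXCL6 had 8.51 in WT 1, 8.53 in WT 3, 8.62 in KO1 4 and 8.41 in KO2 3, and 2.17 to 2.90 in the other 8 libraries, and its relative CXCL8 had 6.48, 6.59, 6.69 and 6.53 in those 4 libraries and 3.36 to 3.798 elsewhere. ADGRG2, an adhesion G protein-coupled receptor, had 7.80 in WT 4, 7.78 in KO1 2, 7.66 in KO2 2 and 7.69 in KO2 4, and 1.19 to 3.43 elsewhere.

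**Figure D3:**
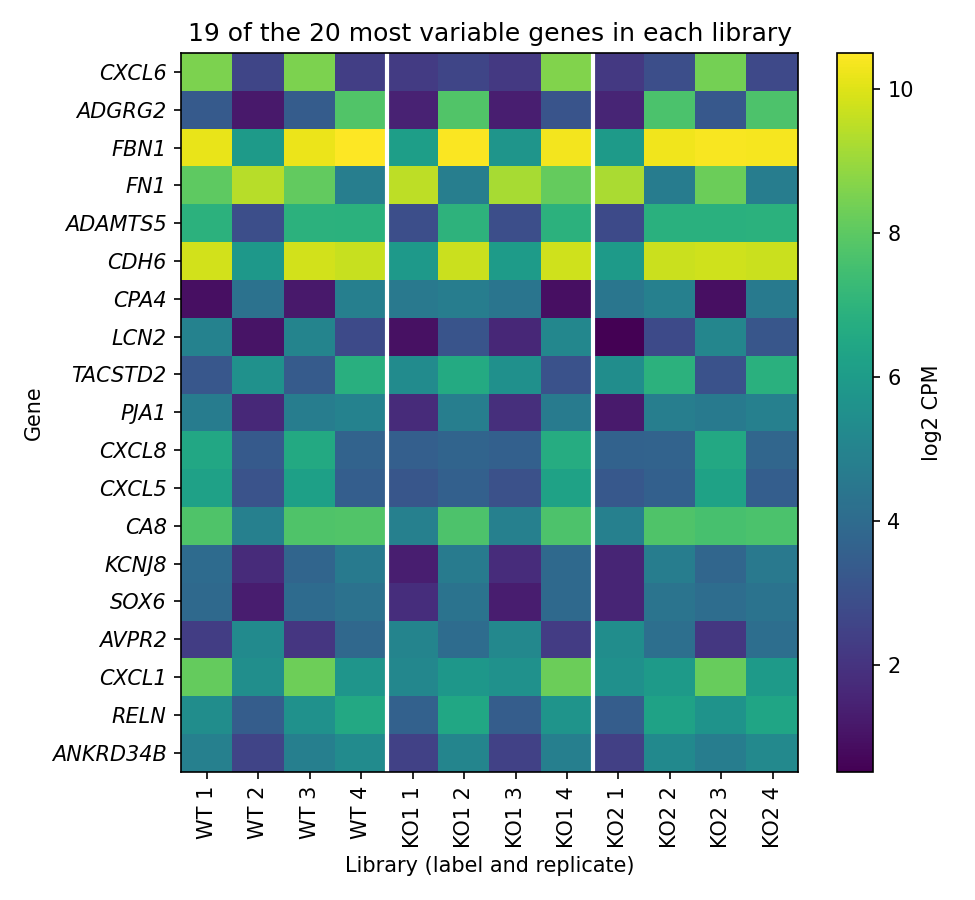
Level in log2 CPM, shown by colour, of 19 of the 20 genes with the largest standard deviation over the 12 libraries, one column per library and white lines between labels. FBN1 lies at 5.74 to 6.12 in WT 2, KO1 1, KO1 3 and KO2 1, and CXCL6 at 8.41 to 8.62 in WT 1, WT 3, KO1 4 and KO2 3.

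Genes of chromosome 13 were higher as a block in 4 libraries. The median over 176 genes of this chromosome of log2 CPM, relative to each gene's median over libraries, was 0.47 in WT 2, 0.52 in KO1 1, 0.52 in KO1 3 and 0.45 in KO2 1. The other 8 libraries lay between −0.11 and −0.01, and 10000 random gene lists matched on size and expression reached at most 0.08 in any library. The same 4 libraries are those with a first component above 43. All 4 windows of 40 genes along the chromosome showed it, at 0.37 to 0.59 in those libraries.

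**Figure D4:**
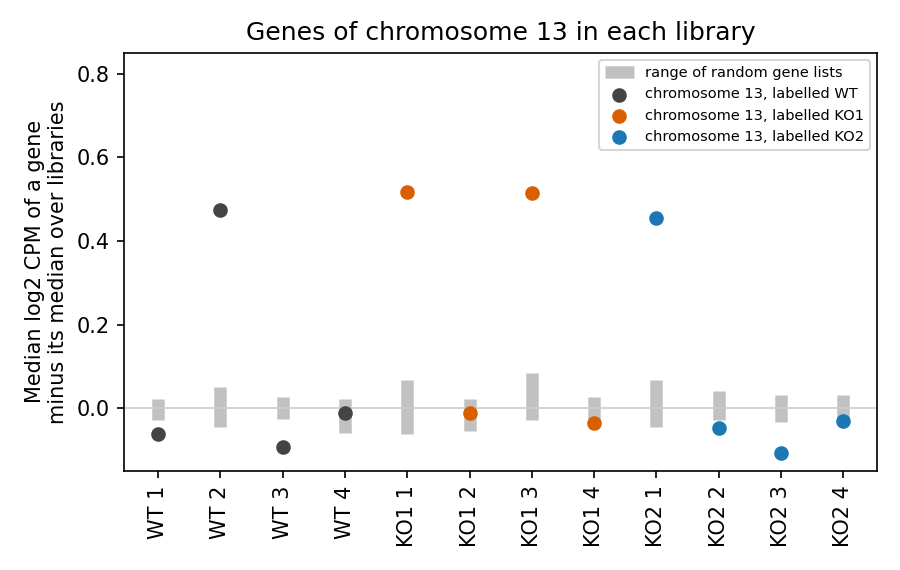
Median over the genes of chromosome 13 of log2 CPM relative to each gene's median over libraries, 1 point per library coloured by label, with grey bars for the range of 10000 random gene lists of the same size and expression. WT 2, KO1 1, KO1 3 and KO2 1 lie at 0.45 to 0.52, above all random lists.

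The libraries labelled KO1 and WT address what 1 knockout clone changes. No gene passed the test, and of the 10 genes nearest to it 9 were lower in KO1 and 1, PABPN1, was higher. RAB43, a small GTPase of Golgi traffic, had 1.247 ± 0.395 CPM (SD, n = 4) in KO1 and 3.53 ± 0.819 CPM in WT, a log2 fold change of −1.50 (SE 0.28, edgeR adjusted p = 0.865). FAM173A, a lysine methyltransferase gene, had 4.35 ± 0.244 against 9.81 ± 2.77 CPM, a log2 fold change of −1.18 (SE 0.23, edgeR adjusted p = 0.865). TMEM250 had a log2 fold change of −0.24 (SE 0.05), ALDH16A1 −0.47 (SE 0.09), SCAND1 −0.86 (SE 0.17), FBXL15 −1.03 (SE 0.23) and the polyadenylation factor PABPN1 0.22 (SE 0.05), all at the same adjusted p. These genes were chosen after their values were seen, by their p.

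By edgeR's quasi-likelihood test 0 of 14302 genes were called in KO1 against WT. At an unadjusted p under 0.05 there were 618 genes, 4.32% of those tested, 155 higher and 463 lower. limma voom called 0 genes and DESeq2 called 5, all lower, namely RAB43, FAM173A, SCAND1, TMEM250 and ALDH16A1 (DESeq2 adjusted p = 0.00202, 0.00428, 0.00699, 0.0219 and 0.0219). For 12409 genes (86.8%) the 95% interval of the fold change lay within 2-fold either way. Without the library WT 4, 38 genes were called, and with 2 components as covariates 244.

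Among the gene lists fixed before the data were examined, genes of proliferation, oxidative phosphorylation and ribosomes were slightly higher in KO1 than in WT relative to other genes by camera with its preset correlation, and were not called with an estimated one. For DNA replication and G1/S genes, 38 of 45 members were higher, with a median log2 fold change of 0.09 (camera adjusted p = 0.000146, and 0.793 with an estimated correlation), among them the clamp loader subunit RFC4 at 0.19 (SE 0.06) and the replication initiation factor CDC45 at 0.19 (SE 0.11). For G2/M genes, 44 of 51 were higher, with a median of 0.09 (camera adjusted p = 0.0034, and 0.793 with an estimated correlation), among them the spindle protein DLGAP5 at 0.16 (SE 0.08). Nuclear oxidative phosphorylation genes were higher in 42 of 60, with a median of 0.06 (camera adjusted p = 0.0127, and 0.793 with an estimated correlation), with the cytochrome oxidase subunits COX7C at 0.13 (SE 0.04) and COX6B1 at 0.26 (SE 0.08), while the complex I subunit NDUFS7 was at −0.49 (SE 0.13). Cytosolic ribosomal protein genes were higher in 56 of 73, with a median of 0.05 (camera adjusted p = 0.0034, and 0.793 with an estimated correlation), and targets of the oxidative stress factor NRF2 in 22 of 27, with a median of 0.11 (camera adjusted p = 0.0311, and 0.793 with an estimated correlation), although the ferritin gene FTH1, which has many pseudogenes, was at −1.27 (SE 0.37). Instead of 5 lists higher, camera called 2 without KO1 1, 1 without KO1 3 or WT 4, 4 without WT 1 or WT 3, and 6 without WT 2, KO1 2 or KO1 4.

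The lists lower in KO1 with the preset correlation were basement membrane and matrix genes, TGF-beta targets, histones and the neighbours of MBOAT7, and none was called with an estimated one. Matrix genes were lower in 29 of 40 members, with a median log2 fold change of −0.06 (camera adjusted p = 0.0212, and 0.793 with an estimated correlation). The collagen gene COL18A1 at −0.47 (SE 0.11) and the heparan sulfate proteoglycan gene AGRN at −0.54 (SE 0.14) were its 2 calls adjusted over the list alone, against 0 over all genes tested. TGF-beta targets were lower in 18 of 25, with a median of −0.07 (camera adjusted p = 0.0109, and 0.431 with an estimated correlation), among them the transcriptional regulator ID1 at −0.38 (SE 0.10) and the SMAD corepressor SKI at −0.24 (SE 0.07). Histone genes were lower in 10 of 11, with a median of −0.21 (camera adjusted p = 0.0311, and 0.793 with an estimated correlation) and 1 call adjusted over the list alone, the variant histone gene H2AFX at −0.62 (SE 0.16). Neighbours of MBOAT7 on chromosome 19 were lower in 10 of 12, with a median of −0.12 (camera adjusted p = 0.0109, and 0.431 with an estimated correlation), among them the tRNA splicing gene TSEN34 at −0.23 (SE 0.08). The median log2 CPM over 514 genes of chromosome 19, relative to each gene's median over libraries, was also low in KO1. It was −0.0984, −0.123, −0.0376 and −0.0504 in KO1 1 to KO1 4. It was 0.015, 0.0372, 0.049 and −0.131 in WT 1 to WT 4, and 0.1, 0.026, 0.0757 and 0.0034 in KO2 1 to KO2 4. Whether the neighbours were lower than the rest of this chromosome was not tested. Instead of 4 lists lower, camera called 1 without KO1 1, 2 without KO1 3, 3 without WT 3 or WT 4, and 7 without WT 2, KO1 2 or KO1 4. No other list had a call adjusted over the list alone.

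Several of these lists also differed between libraries of 1 label. The mean level over members of G1/S genes, relative to each gene's median over libraries, was 0.14 in WT 2, 0.20 in KO1 1, 0.22 in KO1 3 and 0.13 in KO2 1, and −0.07 to 0.00 in the other 8 libraries. For G2/M genes it was 0.23, 0.26, 0.25 and 0.21 in the same 4 libraries, and −0.09 to −0.02 elsewhere. For histones it was −0.67, −0.70, −0.69 and −0.59 in those 4 and −0.06 to 0.31 elsewhere, and for matrix genes −0.19, −0.30, −0.37 and −0.25 against −0.09 to 0.09. Oxidative phosphorylation genes stood at 0.05, 0.06, 0.13 and 0.08 against −0.07 to 0.01, and NRF2 targets at 0.15, 0.11, 0.15 and 0.13 against −0.16 to 0.01. Label KO1 holds 2 of these 4 libraries, and labels WT and KO2 hold 1 each. Without these 4 libraries, a setting chosen after seeing the data, camera called 0 lists in KO1 against WT and 5 in KO2 against WT. Fewer libraries enter that fit, so the lost calls do not show that the fold changes were smaller.

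The libraries labelled KO2 were compared with the same WT libraries. Again no gene passed. DSC2, which encodes the desmosomal cadherin desmocollin-2, had 15.1 ± 1.18 CPM (SD, n = 4) in KO2 and 18.9 ± 1.60 CPM in WT, a log2 fold change of −0.33 (SE 0.08, edgeR adjusted p = 1). The Hedgehog pathway transcription factor GLI2 was at 0.38 (SE 0.10), the Notch target HES1 at 0.42 (SE 0.11), the Fanconi anaemia complex gene FAAP100 at 0.21 (SE 0.05) and the stress-induced gene OSGIN1 at 0.32 (SE 0.09), all at an edgeR adjusted p of 1. These genes were likewise chosen after their values were seen. The edgeR test called 0 of 14302 genes, with 236 (1.65%) at an unadjusted p under 0.05, 167 higher and 69 lower. DESeq2 and limma voom also called 0. The 95% interval lay within 2-fold either way for 12639 genes (88.4%), and with 2 components as covariates 173 genes were called.

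Of the fixed lists, 2 were called in KO2 against WT. Immediate early genes, the fast transcriptional response to growth factor signalling, were higher in 22 of 28 members, with a median log2 fold change of 0.14 (camera adjusted p = 0.0145, and adjusted p = 0.69 with an estimated correlation). Examples are the phosphatase gene DUSP1 at 0.28 (SE 0.09), the transcription factor EGR1 at 0.32 (SE 0.18) and JUN at 0.28 (SE 0.18). Cytosolic ribosomal protein genes were lower in 51 of 73, with a median of −0.03 (camera adjusted p = 0.000377, and adjusted p = 0.858 with an estimated correlation), for example RPL39 at −0.19 (SE 0.07). The mean level of ribosomal protein genes was −0.056 in WT 4, −0.076 in KO1 2, −0.061 in KO2 2 and −0.107 in KO2 4. It was −0.033 to 0.118 in the other libraries of all labels. No member of any list was called adjusted over the list alone or over all genes tested. The mean level over members of immediate early genes was 0.28 in KO2 3, 0.15 in KO2 4, −0.01 in KO2 2 and −0.13 in KO2 1, and between −0.12 and 0.07 in the libraries labelled WT. Camera called 0 lists higher in KO2, and so not this one, without WT 2, without WT 4, without KO2 3 and without KO2 4. With the GC trend removed its adjusted p was 0.0887. In all, camera called 0 lists without KO2 4, 1 without WT 2 and 7 without KO2 1.

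Lists that bear directly on the lipid chemistry of MBOAT7 were not called against WT. Other lysophospholipid acyltransferases and phospholipases were higher in 9 of 21 members in KO1 and in 11 of 21 in KO2, with median log2 fold changes of −0.05 and 0.02 (camera adjusted p = 0.763 and 0.684). The related acyltransferase genes MBOAT2 and LPCAT3 were at 0.12 (SE 0.10) and 0.10 (SE 0.09) in KO1, and at −0.02 (SE 0.10) and 0.04 (SE 0.09) in KO2. Genes of phosphoinositide metabolism had medians of 0.04 and 0.03 (camera adjusted p = 0.44 and 0.349), with the phosphatidylinositol synthase CDIPT at −0.10 (SE 0.07) in KO1 and −0.01 (SE 0.07) in KO2. Components of PI3K, AKT and mTOR signalling had medians of −0.03 and 0.01 (camera adjusted p = 0.525 and 0.815). Arachidonate and eicosanoid genes had medians of 0.03 and −0.04 (camera adjusted p = 0.763 and 0.403), and cholesterol synthesis genes 0.03 and −0.04 (camera adjusted p = 0.763 and 0.409). Targets of hypoxia-inducible factors, which clear cell renal carcinomas often express highly, had medians of 0.03 and −0.05 (camera adjusted p = 0.485 and 0.595). Mesenchymal genes had medians of 0.03 and 0.01 (camera adjusted p = 0.945 and 0.684), and epithelial genes −0.09 and 0.06 (camera adjusted p = 0.196 and 0.684). Over all lists not called, the camera adjusted p lay between 0.0689 for NF-kB and inflammatory genes and 0.945 in KO1, and between 0.0908 and 0.847 in KO2. With components as covariates the NF-kB list, lower in 29 of 35 members in KO1 without them, was called higher in KO1 (camera adjusted p = 0.0385), and in KO2 G2/M genes were called lower and TGF-beta targets higher (camera adjusted p = 0.0234 and 0.0386). The mean level of the NF-kB list was −0.213 in WT 2 against −0.268 and −0.152 in KO1 1 and KO1 3. It was 0.703 and 0.719 in WT 1 and WT 3 against 0.748 in KO1 4, and −0.105 in WT 4 against −0.0897 in KO1 2. Whether its call comes from the covariates was not tested. With the GC trend removed glycolysis was called higher in KO1 (camera adjusted p = 0.0325). Median, mean and test had 1 sign in every called list. They differed in sign for mesenchymal, p53, unfolded protein response, fatty acid and both nephron lists in KO1, for glycolysis, antigen presentation and metallothioneins in KO2, and for phosphoinositide, p53, unfolded protein response, proximal tubule and metallothionein lists in KO1 against KO2.

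A change common to both clones is what the knockout of 1 gene asks for. By edgeR 0 genes were called in the same direction in KO1 and in KO2 against WT, which follows from 0 calls in each comparison. The count was also 0 with the WT libraries split between the clones in each of 6 ways. At an unadjusted p under 0.05, 19 genes moved the same way in both, 14 higher and 5 lower. Independent lists of these sizes would share 1.81 higher and 2.23 lower genes. Both comparisons use the same WT libraries, so the lists are not independent and these counts are no chance value for the 19. In 20 simulations of unchanged groups against the same WT libraries the median was 144.5 shared genes, with a range of 130 to 174, and at most 1 shared call. These simulations drew each library independently and hold none of the 3 sets that cross the labels, so their counts are no chance value for the 19. Of the called lists, ribosomal protein genes were called in both comparisons and in opposite directions, with medians of 0.05 in KO1 and −0.03 in KO2, and in neither with an estimated correlation (adjusted p = 0.793 and 0.858).

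The libraries labelled KO1 and KO2 were compared directly, to show how far the clones differ from each other. All 10 genes nearest to the threshold were lower in KO1, again a choice made after their values were seen. ALDH16A1, of the aldehyde dehydrogenase family, had 9.73 ± 1.133 CPM (SD, n = 4) in KO1 and 16.2 ± 0.804 CPM in KO2, a log2 fold change of −0.73 (SE 0.09, edgeR adjusted p = 0.0624). The palmitoyltransferase gene ZDHHC8 was at −0.41 (SE 0.06), FAAP100 at −0.39 (SE 0.05), the actin regulator MICALL2 at −0.51 (SE 0.07), the ciliary rootlet gene CROCC at −0.83 (SE 0.12) and NME3 at −0.72 (SE 0.11). By edgeR 0 genes were called, with 1545 (10.8%) at an unadjusted p under 0.05, 527 higher and 1018 lower. DESeq2 called 333 genes, 57 higher and 276 lower, and limma voom called 0. Without the library WT 4, which is in neither group and enters through the shared filter, scaling and spread, edgeR called 127. With 2 components as covariates it called 2968.

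Camera called 9 lists in KO1 against KO2 with its preset correlation. With an estimated correlation none of the 9 was called, and the adjusted p lay between 0.366 for TGF-beta targets and 0.758 for G2/M genes. With the preset one, camera called 6 lists without KO1 3, KO2 3 or KO2 4, 8 without KO1 1 or KO2 2, and 11 without KO1 2 or KO2 1. Ribosomal protein genes were higher in 52 of 73 members, with a median log2 fold change of 0.08 (camera adjusted p = 6.9e-06) and 22 calls adjusted over the list alone against 0 over all genes tested, for example RPS27 at 0.33 (SE 0.06) and RPL39 at 0.35 (SE 0.07). G1/S, G2/M and oxidative phosphorylation genes were higher in 40 of 45, 43 of 51 and 42 of 60 members (camera adjusted p = 8.22e-05, 0.00015 and 0.00983), the last with 2 calls adjusted over the list alone. TGF-beta targets were lower in 19 of 25, with a median of −0.08 (camera adjusted p = 0.00108) and 4 calls adjusted over the list alone, ID1 at −0.55 (SE 0.10), SKI at −0.33 (SE 0.07), JUNB at −0.43 (SE 0.11) and TGFB1 at −0.57 (SE 0.15). Immediate early genes were lower in 20 of 28 (camera adjusted p = 0.00194), matrix genes in 27 of 40 (camera adjusted p = 0.0257) with 3 calls adjusted over the list alone, COL18A1 at −0.69 (SE 0.11), AGRN at −0.70 (SE 0.14) and LAMA5 at −0.74 (SE 0.17). Histones were lower in 11 of 11 (camera adjusted p = 0.0441), with 1 call adjusted over the list alone, H2AFX at −0.75 (SE 0.16), and neighbours of MBOAT7 in 10 of 12 (camera adjusted p = 0.0208). With components as covariates histones and oxidative phosphorylation were not called (camera adjusted p = 0.36 for each), and with the GC trend removed the neighbours were not (camera adjusted p = 0.775). With both corrections G1/S and G2/M genes were not called either (camera adjusted p = 0.355 and 0.997). The histone level was −0.70 in KO1 1, −0.69 in KO1 3 and −0.59 in KO2 1, against −0.06 to 0.31 in the other libraries but WT 2. Among lists not called, the counts adjusted over the list alone were 3 each for cholesterol synthesis, fatty acid and triglyceride synthesis, NRF2 targets and lysosomal genes, 2 each for lysophospholipid acyltransferases, phosphoinositide metabolism and glycolysis, 1 for PI3K, AKT and mTOR components, and 0 for the rest, against 0 over all genes tested.

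The fold changes between labels followed the GC content of transcripts. Across 13878 genes with a transcript sequence, 97% of those tested, Spearman's correlation of the log2 fold change with GC was −0.287 in KO1 against WT, 0.341 in KO2 against WT and −0.424 in KO1 against KO2. These correlations are across genes, which are not independent replicates. For each library, the correlation with GC of its deviation from each gene's median over libraries was −0.175, −0.302, −0.128 and −0.234 in KO1 1 to KO1 4, 0.205, 0.178, 0.335 and 0.0538 in KO2 1 to KO2 4, and 0.0094, 0.103, 0.254 and −0.332 in WT 1 to WT 4. It was thus below 0 in each library labelled KO1 and above 0 in each labelled KO2. Transcript GC was 68% for ALDH16A1 and 72.9% for FAM173A, against a median of 50% over all genes.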

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

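Of the tests in this part, those of mislabelled libraries, of an unrecorded technical batch, of leukocytes, fibroblasts or endothelial cells, of library preparation order and, for all lists and for 2 of them alone, of the uneven share of library sets between labels were chosen only after the result was seen. Over 59 quantities and 3 labels, 177 groups of 4 libraries were searched for a library far from the other 3 of its label, and 35 values stood out. Chance gives about 1 group in 20, but not for the genes, components and chromosomes among these quantities, which were chosen because they differ between libraries. They fell 13 times on KO2 1, 11 times on WT 2, 5 times on KO2 3, 4 times on KO1 4, and 1 time each on KO1 2 and WT 4.

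The first principal component was 43.94 in WT 2 and 43.78 in KO2 1, and the chromosome 13 median was 0.474 in WT 2 and 0.454 in KO2 1. In the same order, WT 2 then KO2 1, log2 CPM was 5.957 and 5.94 for FBN1, 2.925 and 2.746 for the aggrecanase gene ADAMTS5, and 5.856 and 5.959 for CDH6. It was 1.659 and 1.242 for PJA1, 4.863 and 4.882 for CA8, and 1.333 and 1.549 for the transcription factor gene SOX6. List levels were 0.141 and 0.134 for G1/S genes and 0.227 and 0.215 for G2/M genes.

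In KO2 1 alone of its label, the list level was −0.367 for epithelial genes, −0.162 for ATF4 targets and 1.15 for metallothioneins. KO1 4 and KO2 3 stood apart with a log2 CPM of 8.619 and 8.413 for CXCL6, 6.691 and 6.53 for CXCL8, and 0.906 and 0.9307 for the carboxypeptidase gene CPA4. KO2 3 also had 6.265 for CXCL5 and 8.186 for CXCL1, and KO1 4 had a level of 0.103 for immediate early genes. WT 2 had a log2 CPM of 7.16 for MBOAT7, against 6.67 to 6.73 in the other libraries labelled WT. The chromosome 8 median was −0.0503 in WT 4, and the level of distal nephron markers was 0.0675 in KO1 2.

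The libraries of each label fall into 3 sets that cross the labels, WT 2, KO1 1, KO1 3 and KO2 1, then WT 1, WT 3, KO1 4 and KO2 3, and then WT 4, KO1 2, KO2 2 and KO2 4. A technical batch alone is argued against by chromosome 13, whose lowest median in the first set was 0.454, above every random list, and admixed leukocytes, fibroblasts or endothelial cells by PTPRC, TYROBP, COL1A2, COL3A1 and PECAM1, at most 0.25 CPM in any library. An earlier bound of 10 CPM was passed by CD68 at up to 34.94 CPM, COL1A1 at up to 11.71 CPM, PDGFRB, at 9.155 to 10.54 CPM in the second set and 15.93 to 20.56 CPM in the others, and ENG, at 108.6 to 139.6 CPM in the first set and 61.45 to 76.63 CPM in the others, but each of these 4 genes was above 4 CPM in all 12 libraries, so that bound decides nothing, and cells of another type outside these lists stay open. A candidate explanation that stays open is that labels are attached to other libraries than intended, since the label held 12.31% of the variance, less than the median partition, but sets spread evenly over correct labels would give that too, and the third component was above 0 in each library labelled KO1 and below 0 in each labelled KO2, while the correlation with GC had the opposite signs. Sublines of Caki-1 that differ in chromosome content within each label are another, for which no separate test was run. The knockout, the only biological difference the design names, runs along the labels, which these sets cross. This speaks about the knockout only if the labels are right. With labels attached to other libraries than intended, the sets could follow the knockout, so it is not set aside here.

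With the first 2 components as covariates, edgeR called 2968 genes in KO1 against KO2, 1313 higher and 1655 lower, with a median absolute log2 fold change of 0.18 and 93.2% under 1.5-fold. Of 35 splits of these 8 libraries 1, the real one, called as many, and the highest other called 28. This argues against chance for the count, but not for single genes, because the components were taken from the same expression values. CXCL6, the reported protein-coding gene of smallest p, was at 0.66 (SE 0.05). Its log2 CPM was 2.25 and 2.17 in KO1 1 and KO1 3 against 2.17 in KO2 1. It was 8.62 in KO1 4 against 8.41 in KO2 3, and 2.594 in KO1 2 against 2.904 and 2.705 in KO2 2 and KO2 4. How many calls come from the covariates was not tested. With the GC trend also removed 1455 genes were called, 948 of them among the 2968, a count between the bounds set beforehand for and against GC bias, and over the 2020 genes lost the median absolute log2 fold change went from 0.164 to 0.0649 while the median SE went from 0.0444 to 0.0409, so those calls ended because the fold changes shrank. Spearman's correlation across genes of the fold change with GC in that fit was −0.524, and library preparation order cannot be told apart from the label, because that order is not given in the sources used here. A difference between the clones stays open as well, and was not tested apart from that order.

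Of the 11 list calls in KO1 or KO2 against WT, 4 were kept in the same direction with components as covariates, where the median log2 fold change (quartiles over members) went from 0.09 (0.06 to 0.14) to 0.04 (0.00 to 0.07) for G1/S genes, 0.05 (0.00 to 0.09) to 0.03 (−0.01 to 0.09) for ribosomal proteins and −0.12 (−0.22 to −0.07) to −0.12 (−0.17 to −0.04) for neighbours of MBOAT7 in KO1, and 0.14 (0.02 to 0.24) to 0.10 (0.04 to 0.26) for immediate early genes in KO2. In the other 7 it went from 0.09 (0.04 to 0.11) to 0.01 (−0.02 to 0.04) for G2/M genes, 0.06 (−0.04 to 0.11) to 0.03 (−0.03 to 0.08) for oxidative phosphorylation, 0.11 (0.02 to 0.15) to 0.02 (−0.01 to 0.05) for NRF2 targets, −0.21 (−0.25 to −0.08) to −0.05 (−0.16 to 0.03) for histones, −0.06 (−0.33 to 0.01) to −0.01 (−0.12 to 0.02) for matrix genes and −0.07 (−0.27 to 0.00) to −0.03 (−0.22 to 0.03) for TGF-beta targets in KO1, and −0.03 (−0.08 to 0.01) to −0.02 (−0.08 to 0.03) for ribosomal proteins in KO2, where camera adjusted p became 0.71, 0.369, 0.334, 0.376, 0.0684, 0.0684 and 0.198, and since the median SE of members fell as well and camera ranks members against all other genes, why each call ended is not settled by the smaller fold changes. An uneven share of the 3 library sets between labels may therefore account for G2/M genes, NRF2 targets and histones, and is left open for the rest. The medians of immediate early genes in KO2 and neighbours of MBOAT7 in KO1 stayed at 0.102 and −0.117. Whether the share is the whole cause for these 2 lists was asked only after their calls were seen to stay. Camera's call was part of that test, so it cannot decide. Among the rest, the level of TGF-beta targets was 0.017 in WT 2 against −0.209 and −0.139 in KO1 1 and KO1 3. It was −0.0149 and −0.0182 in WT 1 and WT 3 against −0.1 in KO1 4, but −0.142 in WT 4 against −0.124 in KO1 2. With the GC trend removed 9 of the 11 were kept, all but immediate early genes in KO2 and neighbours of MBOAT7 in KO1, a count between the bounds set beforehand. The medians of these 2 lists (quartiles over members) were then 0.075 (0.009 to 0.228) and −0.076 (−0.131 to −0.005), smaller but of the same sign. With both corrections 1 was kept, immediate early genes in KO2, so a part played by GC content cannot be told apart from the labels. An effect of the knockout stays open, untested apart from these.

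For the 3 comparisons by label without covariates, edgeR called 0 genes in the real split of the 8 libraries and 0 in the highest other. A count of 0 is reached by every split whatever the data, here 35 of 35 in each comparison, so these splits say nothing about chance. At an unadjusted p under 0.05 there were 618, 236 and 1545 genes, and DESeq2 called 5, 0 and 333 and limma voom 0 in each.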

How the results depend on the processing

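Tests with components or surrogate variables as covariates, with the GC trend removed or without the 4 libraries that stand apart on the first component were chosen only after the result was seen. No paired analysis was possible because the labels give no replicate numbers that groups share. By edgeR 0 genes were called in each comparison, with 618, 236 and 1545 at an unadjusted p under 0.05, and limma voom called 0. In KO1 against WT, DESeq2 called 5 genes, components as covariates gave 244, surrogate variables 256, and components with the GC trend removed 129. In KO2 against WT, components gave 173, surrogate variables 157 and both corrections together 26, while DESeq2 called 0. In KO1 against KO2, library totals gave 4, the CPM filter 4, DESeq2 333, a fit of only the 2 groups 8, components 2968, surrogate variables 3073 and components with the GC trend removed 1455. Leaving out each library gave 0 to 38 genes in KO1 against WT and 0 to 127 in KO1 against KO2, both highest without WT 4, and 0 throughout in KO2 against WT. The count of genes called the same way in both clones was 0 under every setting run. It could only be 0 where KO2 against WT called no gene. Apart from the splits of WT libraries, that held in all settings but components, surrogate variables and both corrections together. The MBOAT7 log2 fold change in KO1 was 0.04 and turned to −0.07829 with components, −0.06575 with surrogate variables and −0.01084 without the 4 libraries. It ran from −0.04791 without KO1 3 to 0.166 without WT 2, and was −0.003915 without WT 1 and −0.007343 without WT 4. In KO2 it was 0.1708 with components and 0.1643 with surrogate variables (edgeR adjusted p = 0.0389 and 0.0306), 0.08002 with components and the GC trend removed (edgeR adjusted p = 0.353), 0.1212 with only the GC trend removed, against 0.1225 in KO1, and 0.08101 to 0.3134 when each library was left out. Camera called 9, 2 and 9 lists in KO1 against WT, KO2 against WT and KO1 against KO2. An estimated correlation gave 0, 0 and 0, fry 0, 0 and 1, and leaving out the 4 libraries 0, 5 and 3. Components gave 4, 3 and 7, GC removal 9, 1 and 11, and both corrections together 1, 1 and 6. Leaving out each library gave 3 to 13 lists in KO1 against WT (3 without KO1 1 or KO1 3, 4 without WT 4, 13 without WT 2), 0 to 7 in KO2 against WT (0 without KO2 4, 1 without WT 2, 7 without KO2 1, and none higher without WT 2, WT 4, KO2 3 or KO2 4) and 6 to 11 in KO1 against KO2. The 30 nearest gene results, chosen by their p in these same libraries, kept their direction under every setting run, which is no independent support. The cause of these changes was not tested, except that fewer libraries enter a fit that leaves some out. In simulated counts 47% of changes of 1.5-fold were recovered in KO1 against WT. Those counts hold none of the 3 library sets, so this is not the recovery in the real comparison.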

Other observations

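Gene groups outside the comparisons also followed the 3 sets of libraries that cross the labels. The NF-kB and inflammatory list holds genes such as neutrophil chemokines and acute phase genes, and members with large shifts, such as CXCL6, weigh on its mean. Its mean level over members was 0.70 in WT 1, 0.72 in WT 3, 0.75 in KO1 4 and 0.74 in KO2 3, and −0.27 to −0.04 in the other 8 libraries. SAA2, an acute phase gene, had a log2 CPM of 6.93, 6.95, 7.02 and 6.82 in those 4 libraries and 4.52 to 4.88 elsewhere. Metallothioneins, which bind zinc and copper, stood at 0.94 in WT 2, 1 in KO1 1, 0.998 in KO1 3 and 1.15 in KO2 1, and −0.31 to 0.25 elsewhere, while epithelial genes stood at −0.47, −0.47, −0.45 and −0.37 in those 4 and −0.02 to 0.13 elsewhere. Interferon-stimulated genes stood at 0.17 in WT 4, 0.13 in KO1 2, 0.15 in KO2 2 and 0.14 in KO2 4, and −0.14 to 0.02 elsewhere. Glycolysis genes stood at −0.19, −0.16, −0.11 and −0.14 in these last 4 libraries and at 0.20, 0.22, 0.23 and 0.20 in WT 2, KO1 1, KO1 3 and KO2 1. The drug efflux transporter gene ABCB1 had a log2 CPM of 5.33 in WT 4, 5.29 in KO1 2, 5.33 in KO2 2 and 5.5 in KO2 4, and 2.81 to 3.63 elsewhere.

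Blocks of neighbouring genes on other chromosomes differed in the same way, as medians over windows of 40 genes. On chromosome 7, the window from TMEM178B to XRCC2 stood at 0.69 in WT 2, 0.66 in KO1 1, 0.66 in KO1 3 and 0.73 in KO2 1, and at −0.59 in WT 4, −0.62 in KO1 2, −0.50 in KO2 2 and −0.50 in KO2 4, with −0.05 to 0.04 in the remaining 4 libraries. On chromosome 8, the 3 windows from FBXO25 to THAP1 stood between −0.52 and −0.43 in WT 4, KO1 2, KO2 2 and KO2 4. On chromosome 10, the 2 windows from ZMYND11 to MTPAP stood between 0.32 and 0.41 in WT 2, KO1 1, KO1 3 and KO2 1, and on chromosome 15 the window from FRMD5 to PIGB stood between 0.40 and 0.46 in those libraries. The third principal component, with 6.42% of the variance, was positive in each library labelled KO1, at 16.02, 8.21, 9.50 and 14.1, and negative in each labelled KO2, at −14.9, −12.6, −6.47 and −9.07, with 1.47, −11.5, −2.39 and 7.67 in the libraries labelled WT.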
